A study of Drosophila melanogaster with 14 samples.

How the data were processed

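RNA was taken with Trizol from pools of 100 embryos (lola-F set) or 10 adult flies (lola-O set), and 1 µg of total RNA per sample was made into directional libraries, per the labels' protocols; the pool size of the lola-null set is not given in the sources used here. Embryos were collected for 2 h at 25 °C and aged for 13 h, and lola-F and lola-null embryos were sorted by hand for mCherry, per the series' design text; the protocols in the labels name this collection for lola-F alone. Whether the lola-null set has the age on its labels is in doubt, because its controls differ widely from the lola-F controls. Groups and replicate numbers follow the labels. Nothing in the labels says that replicates came from separate crosses or collections, so p-values measure only the spread between these samples, which may be technical.

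The authors aligned reads with STAR 2.5.0c and counted them with HTSeq 0.6.1p1 on BDGP6, per the submitters' processing notes. The annotation release and the strand setting of the counting are not given in the sources used here. Each deposited file holds gene counts of 1 library, whole numbers without normalization, followed by 5 summary rows. The deposited files of both embryo sets, but not those of the adults, are named as filtered; what was filtered, reads or genes, is not given in the sources used here. These rows hold reads assigned to no gene, to several genes or to several places, and they stayed out of library sizes and tests. They made up 6.32% to 9.41% of reads in the lola-O libraries and in all lola-F libraries but control 1 (66.7%), and 18.6% to 44.5% in the lola-null libraries. In lola-F control 1, 65.2% of reads mapped to several places. Reads shared between near-identical genes are therefore missing from the counts, and values of multigene families (Jon, Mal-A, Twdl, Cpr, Obp, actin and histone genes) are uncertain to that extent. Library totals and the list of genes with their depth set the precision: the shallowest library holds 3326811 counts, and floors of 3 counts cover counting error only.

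The lola-F and lola-O files list 17558 gene identifiers and the lola-null files 17387. The other 171, nearly all ribosomal RNA genes, enter no comparison that includes the lola-null set. Of the identifiers, 17252 matched the BDGP6.54 annotation, which gave symbols and positions, and 306 did not. One of these, FBgn0005630, was read as a former identifier of lola from general knowledge, not from a table; the other 305 kept their identifiers and so are missing from gene lists.

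Each set was analysed on its own in R 4.3.3 with edgeR 4.0.16: genes were filtered with filterByExpr, libraries scaled by TMM, and mutants compared with the controls of their set by the quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05. The same test was run on the interaction of the 2 embryo sets (10 libraries) and between their controls. Standard errors are the log2 fold change divided by the square root of F. The expression level of lola was also compared by an exact permutation test. The 33 gene lists, the rule for named genes, the tests and most of the alternatives were fixed before the data were examined; which list members the text names was chosen among those the rule allows after their values were seen. Lists with 5 or more tested genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01, 91 tests in 1 adjustment. Camera with an estimated correlation and fry were alternatives. Named genes were 7 fixed genes (lola, Tbh, Tdc2, Spn88Ea, roX1, roX2 and Yp1), the 8 named genes with the largest rise and the 8 with the largest fall past the threshold at 5 CPM or more without overlap between groups, the 2 largest changes of any symbol in each direction, up to 3 members of each list with the smallest p, and the 5 interaction genes with the smallest p.

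All pairs of libraries within a group differed by more than sampling noise (chi-square per degree of freedom 3.18 to 89.9), so none was treated as 1 library deposited more than once; separate preparations of 1 RNA pool are not excluded by this. lola-F mutants 1 and 2 were the closest pair (3.18, against 71.1 and 89.9 for the other mutant pairs), and with either left out no gene passed in edgeR (2595 genes without mutant 1 and 2874 without mutant 2 at an unadjusted p under 0.05; DESeq2 on all 6 libraries called 810 higher and 1112 lower). Replicate numbers were not used to pair libraries. On simulated counts with the means, spread and depth of each set, the test recovered 39%, 6% and 38% of 100 genes changed 2-fold and 89%, 62% and 92% of 100 genes changed 4-fold in the lola-F (10075 genes), lola-null (9121) and lola-O (12812) sets. It called 9, 9 and 26 unchanged genes. For the interaction (10721 genes), 0% and 18% were recovered, with 2 unchanged genes called, and between controls (10326 genes) 7% and 71%, with 8. A 40-gene list raised in the simulation was called in each case but the interaction (adjusted p = 0.0782). The simulation drew each gene on its own, without correlation between genes or a length trend. It therefore does not gauge list calls in the real data, where list members vary together.

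Alternatives were DESeq2 size factors, upper quartile scaling, no filter on low counts, a filter at 5 CPM, DESeq2 1.42.0, limma-voom, each library left out, a fit of all 14 libraries, a replicate block and a minimum log2 fold change of 1. A correction of each library for exonic length by loess, tried in 1 form only, and a block with crossed numbers in the lola-null set, were added after seeing the data. Exonic length joined the exons of all isoforms of a gene.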

Results

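RNA sequencing was carried out on whole Drosophila melanogaster animals carrying mutations in lola (longitudinals lacking), a gene that encodes many isoforms of a zinc finger transcription factor of the BTB family with known roles in axon guidance. The 14 libraries fell into 3 sets, each with mutant and control animals. In every set the second copy of the region was the deficiency Df(2R)ED2076, so that the mutants carried a mutant chromosome and the controls a wild-type chromosome over the same deficiency. The lola-F set held 3 mutant and 3 control libraries of embryos, and the lola-null set held 2 and 2 libraries of embryos. Both embryo sets were labelled as 15 h after fertilization, an age that the data leave in doubt for the lola-null set, since the controls of the 2 sets differed in 7381 of 10501 genes (70.3%). The lola-O set held 2 mutant and 2 control libraries of adults frozen within 10 h of eclosion. Gene counts per library ranged from 3326811 (lola-F control 1) to 22629694 (lola-F mutant 3) in the lola-F set, from 4178333 to 7098985 in the lola-null set and from 10078884 to 15960133 in the lola-O set. Levels are given as CPM, counts relative to the scaled library size of the set, as mean ± SD, with n = 3 per group in the lola-F set and n = 2 per group in the other sets.

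lola itself, the mutated gene, was the first measurement of each set, since it checks the labels. It lies on chromosome 2R, 10481894 to 10543291, on the minus strand of the BDGP6.54 annotation, and was listed in the files under a former FlyBase identifier, FBgn0005630. In lola-F mutant embryos lola was at 180.3 ± 47.9 CPM against 298.1 ± 55.1 in controls, 60.5% of the control level, with every mutant library below every control library. The exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow, and the adjusted p over all genes was 0.0796 (0.0322 without mutant 3, and 0.0141 in DESeq2). In lola-null mutant embryos the level was 706.6 ± 477.2 CPM against 1215 ± 281, and the 2 mutant libraries stood apart: the library labelled null mutant 1 held 1044 CPM, inside the range of the controls (1016 and 1414), and the library labelled null mutant 2 held 369.2 CPM. The exact permutation p was 0.667, with 0.333 the smallest possible, and the adjusted p was 0.338. TwdlM and Sxl, given below, were at like levels in both null mutants. Both genes were picked from calls that favour genes alike in the 2 mutants, so they cannot check this label. Without the library labelled null mutant 1 lola fell by 1.82 on the log2 scale (adjusted p = 1.67e-05), and without null mutant 2 the log2 fold change was −0.20 (adjusted p = 0.723). In lola-O adults lola did not pass (111.4 ± 2.71 against 110.9 ± 19.8 CPM, adjusted p = 0.993). A gene-level count sums all isoforms, so a change in 1 isoform need not lower it. With the trend of each library with exonic length removed, a setting chosen after seeing the data, the log2 fold change of lola was positive in all 3 sets (0.76, 0.84 and 0.78), without a call. That length joined the exons of all isoforms, so it can exceed the transcript length of a gene with many isoforms, such as lola. These values thus neither show nor exclude that the lower lola counts came from length. The 2 null mutants also differed in this trend. Spearman's rho between a gene's deviation from its set mean and its length was −0.09 in mutant 1 and −0.61 in mutant 2. In the null controls it was 0.37 and 0.53. Whether the trend gave the lower lola level of null mutant 2 was not tested.

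**Figure D1:**
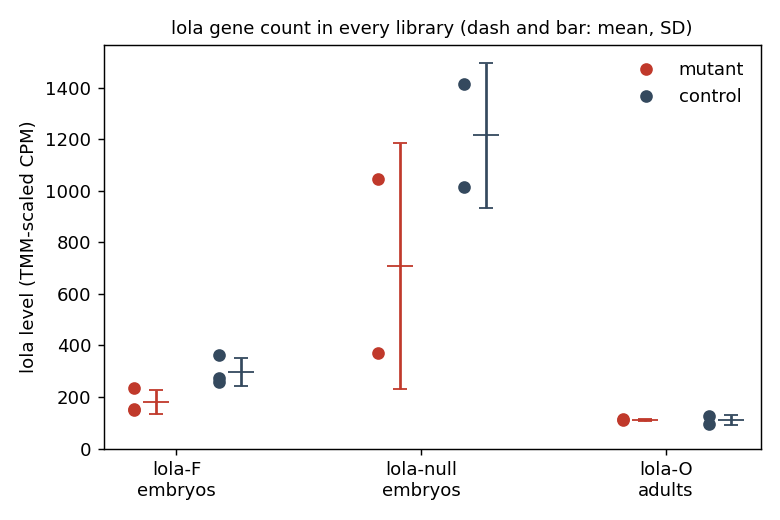
Level of lola in each of the 14 libraries (y axis, TMM-scaled CPM; each set scaled on its own). Points are libraries, the dash and bar are the mean and SD; the library labelled null mutant 1 (1044 CPM) lies among the controls of its set, whereas the 3 lola-F mutants lie below their controls.

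The first comparison asked which genes change in embryos when the lola-F isoform is lost. In lola-F mutant embryos 16 of 53 midgut digestive enzyme genes, 11 of 72 cuticle genes and 26 of 83 ribosomal protein genes passed as higher, and 6 of 22 neuron genes and 6 of 37 axon guidance genes as lower. Camera called each of these 5 lists, and none with an estimated correlation (adjusted p = 0.783 for each). The lipase gene Lip1 rose 5.29-fold, from 9.351 ± 1.182 to 50.03 ± 6.872 CPM (adjusted p = 0.00763), and the maltase gene Mal-A1 rose 3.15-fold, from 230.1 ± 20.7 to 725.5 ± 20.2 CPM (adjusted p = 0.00763). The cytokine gene upd3, a ligand of the JAK/STAT pathway, fell 9.48-fold, from 7.86 ± 1.35 to 0.8008 ± 0.3497 CPM (adjusted p = 0.0153), and ple, the tyrosine hydroxylase gene of dopamine synthesis, fell 3.59-fold, from 143 ± 46.7 to 39.8 ± 9.20 CPM (adjusted p = 0.0247). Of 10191 genes tested, 339 were higher and 380 lower, 105 and 234 of them by more than 2-fold. Without mutant 1, mutant 2, control 1 or control 2 no gene passed in edgeR, although 2595, 2874, 2277 and 2551 genes had an unadjusted p under 0.05. Without control 3, 646 genes were lower. DESeq2 on all 6 libraries called 810 higher and 1112 lower.

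Among the genes with large rises, at 5 CPM or more in a group, were the serine protease gene Jon44E (3.60-fold, 159.3 ± 28.8 to 574.6 ± 202 CPM), the small heat shock gene l(2)efl (3.48-fold), the sterol-binding gene Npc2c (3.47-fold), the photolyase gene phr (3.47-fold), the Tweedle cuticle gene TwdlJ (3.39-fold), the maltase gene Mal-A7 (4.35-fold) and the alkaline phosphatase gene Alp7 (6.58-fold). Alp7 varied widely among the mutants, at 75.0 ± 69.2 CPM against 11.3 ± 2.03. The unnamed gene CG13135 rose 36.7-fold, from 0.739 ± 0.198 to 29.0 ± 20.3 CPM. Among genes at 5 CPM or more in a group, falls besides upd3 and ple included the ETS factor gene Ets21C (4.79-fold), phu (3.87-fold), the topoisomerase gene Top3alpha (3.57-fold), dpy (3.48-fold), which encodes a giant extracellular matrix protein, the potassium channel gene eag (3.42-fold) and srl (3.28-fold), the fly PGC-1 homologue. CG43175 fell 10.6-fold and CG10081 10.2-fold. The adjusted p-values of these genes ran from 0.0153 to 0.0462. Without mutant 3, Ets21C, phu, eag, srl and CG43175 did not pass (adjusted p = 0.0761, 0.0803, 0.0658, 0.0670 and 0.0655), and without control 3 Alp7 did not (0.0687).

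Of 53 midgut digestive enzyme genes, 16 rose and none fell (22 rose when adjusted over the list alone), among them Mal-A6 (2.27-fold) and Mal-A8 (2.66-fold). Of 83 ribosomal protein genes, 26 rose and 57 did not pass (78 adjusted over the list alone), with RpLP0 at 3437 ± 723 against 1779 ± 230 CPM. Of 72 cuticle genes, 11 rose and none fell (16 higher and 1 lower adjusted over the list alone), led by TwdlN (2.84-fold), Cpr11B (1.85-fold) and Cpr64Ad (2.67-fold). Of 38 olfaction and gustation genes 3 rose, all of them odorant-binding protein genes: Obp99c (1.95-fold), Obp58c (1.97-fold) and Obp56h (1.69-fold). For olfaction the count adjusted over the list alone was also 3. Camera called these 4 lists higher, with adjusted p = 3.75e-13 for midgut, 1.91e-26 for ribosomal proteins, 0.00127 for cuticle and 0.00579 for olfaction. Each lost its call with an estimated correlation (adjusted p = 0.783 for each), and without control 3 the cuticle list also lost it (adjusted p = 0.263) and RpLP0 did not pass (0.0510). With the length trend of each library removed, the cuticle and olfaction lists lost their calls (adjusted p = 0.377 and 0.148), and the midgut and ribosomal lists kept theirs (2.60e-09 and 7.00e-21).

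Of 22 neuron genes, 6 fell and none rose (14 fell adjusted over the list alone), and all 22 had a negative fold change. They included futsch, a microtubule-associated protein of axons (3.12-fold, 128.3 ± 47.4 to 41.2 ± 7.19 CPM), the pan-neuronal RNA-binding gene elav (2.09-fold) and the synaptic release gene unc-13 (2.64-fold). Of 37 axon guidance genes, 6 fell and none rose (18 fell adjusted over the list alone), among them PlexA, a semaphorin receptor (2.40-fold), Sema1a (2.74-fold) and the Slit receptor robo2 (1.86-fold). Of 18 dopamine and serotonin genes, ple and the receptor gene Dop1R1 (2.48-fold) fell (3 adjusted over the list alone). Antimicrobial peptide genes had 1 member of 21 that fell, AttC at 0.0543 ± 0.0941 against 2.07 ± 0.815 CPM, and 4 adjusted over the list alone. The hemocyte list (14 genes, lz lower; 7 adjusted over the list alone) and the ecdysone and juvenile hormone list (22 genes, EcR 1.73-fold lower; 0 adjusted over the list alone) had 1 called member each. Camera called these 6 lists lower, with adjusted p = 1.10e-07 for neuron, 1.52e-08 for axon guidance, 0.00614 for dopamine and serotonin, 0.000225 for antimicrobial peptides, 0.0204 for hemocyte and 0.0225 for ecdysone. None kept its call with an estimated correlation (adjusted p = 0.783 for each). Without mutant 3 the hemocyte and ecdysone lists lost their calls (adjusted p = 0.215 and 0.122), as did the ecdysone list without control 3 (0.151). Sema1a, lz and EcR did not pass without mutant 3 (adjusted p = 0.0590, 0.0757 and 0.0520), nor EcR without control 3 (0.0573). With the length trend removed, the axon guidance, dopamine and serotonin, hemocyte and ecdysone lists lost their calls (adjusted p = 0.372, 0.0728, 0.987 and 0.875), and the neuron and antimicrobial peptide lists kept theirs (0.00738 and 1.65e-06).

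Octopamine genes, a pathway of interest for lola-F, were not called as a list (12 genes, adjusted p = 0.0661), with 1 member lower, also over the list alone, the receptor gene Octalpha2R (2.44-fold, adjusted p = 0.0420, but 0.0554 without mutant 3 and 0.0525 without control 3). Tbh, which encodes the enzyme that makes octopamine, was at 22.6 ± 2.97 against 26.1 ± 6.88 CPM (log2 fold change −0.22 ± 0.21 SE, adjusted p = 0.499), and Tdc2 at 11.2 ± 0.277 against 10.2 ± 1.37 CPM (adjusted p = 0.683). Muscle genes moved both ways: 7 of 23 rose, such as Act87E (2.44-fold) and Mp20 (1.94-fold), and 3 fell, such as Msp300 (3.06-fold), against 11 and 5 adjusted over the list alone.

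Called genes differed in transcript length. Genes higher in lola-F mutants had a median exonic length of 1293 bases and genes lower a median of 6582 bases, against 2068 bases for all genes, and the log2 fold change across 9995 genes ran with length at Spearman's rho = −0.50, genes not being independent replicates. With the length trend of each library removed, a setting chosen after seeing the data, 166 genes were higher and 87 lower (65.6% higher), and the falls of dpy, Msp300 and EcR turned to log2 fold changes of 0.0065, 0.22 and 0.06. Of the 45 named genes that passed, 23 kept their direction but did not pass with this correction, besides the 3 that turned. Upper quartile scaling shifted the median log2 fold change of all genes from 0.02 to 0.17 and the split to 943 higher and 439 lower (68.2% higher, against 47.1%).

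The second comparison asked which genes change in embryos without lola function. In lola-null mutant embryos 62 of 68 cuticle genes passed as higher than in controls, with a median log2 fold change of 5.61 over the list. Of the neuron list 13 of 21 genes passed as lower, of axon guidance 12 of 37, of the ecdysone and juvenile hormone list 9 of 21 and of the germline list 10 of 21. Camera called each of these 5 lists, and none with an estimated correlation (adjusted p = 0.783 for each). The Tweedle gene TwdlM rose from 2.15 ± 0.339 to 553.9 ± 4.13 CPM (257-fold, adjusted p = 5e-10), TwdlL from 0.640 ± 0.325 to 190 ± 10.5 CPM (305-fold) and the cuticle gene Cpr65Ea from 1.17 ± 0.497 to 391 ± 131 CPM (341-fold). The calcium channel gene cac fell 12.9-fold, from 25.1 ± 11.9 to 1.82 ± 1.13 CPM (adjusted p = 2.57e-05), and Sxl, the sex determination switch gene, fell 9.85-fold, from 182.6 ± 19.04 to 18.62 ± 5.25 CPM (adjusted p = 4.15e-06). Of 9288 genes tested, 689 were higher and 881 lower, each by more than 2-fold. The library labelled null mutant 1, in which lola was at control level, entered as a mutant throughout. With both embryo sets scaled together, its TwdlM (563 CPM) and Sxl (15.1) lay near those of null mutant 2 (482 and 19.55). The null controls held 2.00 and 1.59 CPM of TwdlM and 141 and 163 of Sxl. The test that called both genes favours such agreement of the mutants, so it does not check the label of null mutant 1. The gene psq, like lola, was at control level in null mutant 1 (200 CPM, against 52.35 in null mutant 2 and 189 and 231 in controls).

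Of 68 cuticle genes, 62 rose and none fell (63 adjusted over the list alone). Their median log2 fold change was 5.61, or 5.35 with the 8 genes without control counts at a floor of 3 counts over the control group. Against that floor, Cpr65Ec was at least 146-fold higher, Cpr64Ab at least 125-fold and Cpr67Fa1 at least 63.5-fold. Ccp84Ae was at least 55.2-fold higher (33.6-fold without the library labelled null mutant 1) and TwdlQ at least 48.3-fold. Outside the list, Tb was at least 144-fold, polyph at least 118-fold and Acbp4 at least 55.5-fold higher. Of 26 chitin and cuticle formation genes, 8 rose and 2 fell, also over the list alone, led by Vajk4 (42.9-fold), Vajk1 (41.2-fold) and Vajk2 (18.9-fold). Of 20 midgut enzyme genes, 10 rose and 1 fell (11 and 1 adjusted over the list alone), with Jon65Aiii at 15.25 ± 1.602 against 0.342 ± 0.483 CPM and Jon65Aiv at 8.28 ± 3.36 against 0.503 ± 0.518. Of 103 detoxification genes, 25 rose, such as Ugt37B1 (7.58-fold) and Cyp6a23 (5.29-fold), and 2 fell, such as Cyp4p2 (21.4-fold), against 30 and 3 adjusted over the list alone; Cyp6a23 did not pass without control 2 (adjusted p = 0.0559). The ribosomal protein list was called higher (82 genes, median log2 fold change 0.71), but its only called member, RpL22-like, was lower (0 adjusted over the list alone). Camera called these 5 lists higher, with adjusted p = 1.32e-96 for cuticle, 3.09e-05 for chitin, 6.10e-05 for midgut, 0.000834 for detoxification and 0.00297 for ribosomal proteins; with an estimated correlation none passed (adjusted p = 0.783 for the first 4 and 0.923 for ribosomal proteins). With the length trend removed the ribosomal list turned lower, without a call (adjusted p = 0.889), and the detoxification list lost its call (0.103). Without null mutant 2 the ribosomal and detoxification lists lost their calls (adjusted p = 0.789 and 0.0704), and without control 2 the ribosomal list did (0.0805).

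Of 21 neuron genes, 13 fell and none rose (13 over the list alone), among them fne, an RNA-binding gene of the ELAV family (8.04-fold), and nSyb, a synaptic vesicle gene (7.04-fold, 32.6 ± 5.89 to 4.55 ± 0.985 CPM). Of 37 axon guidance genes, 12 fell and none rose (13 over the list alone), led by Sema1a (8.15-fold, 140.8 ± 9.36 to 17.2 ± 0.416 CPM), Sema2b (9.19-fold) and NetB (5.08-fold). Of 21 ecdysone and juvenile hormone genes 9 fell (12 over the list alone), including the nuclear receptor genes Hr3 (11.1-fold) and Eip75B (7.46-fold). Of 21 germline genes 10 fell (11 over the list alone), such as ovo (9.53-fold), and of 17 neuroblast genes 5 fell and 1 rose (6 and 1 over the list alone), with scrt (7.17-fold) and grh (4.76-fold) among the falls. Of 13 Turandot and heat shock genes 3 fell (4 over the list alone), all of them heat shock genes, led by Hsp27 (10.5-fold). Camera called these 6 lists lower, with adjusted p = 1.88e-07 for neuron, 4.08e-07 for axon guidance, 2.03e-05 for ecdysone, 0.00038 for germline, 0.0204 for neuroblast and 0.0383 for heat shock. With an estimated correlation none passed (adjusted p = 0.783, and 0.804 for heat shock). The neuroblast list lost its call without the library labelled null mutant 1 (adjusted p = 0.0510) or control 2 (0.0652), and the heat shock list without null mutant 1 (0.109) or control 1 (0.422). With the length trend removed, the axon guidance and neuroblast lists lost their calls (adjusted p = 0.180 and 0.476). The tracheal list was not called (adjusted p = 0.0911), with vvl (6.57-fold), rho (9.85-fold) and trh (2.36-fold) lower (3 over the list alone); trh did not pass without null mutant 2, control 1 or control 2 (adjusted p = 0.0798, 0.423 and 0.343).

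Among the named genes that fell, SNCF was at 0 CPM in both mutants and 16.8 ± 13.9 in controls, at least 56.0-fold lower against a floor of 3 counts over the mutant group, and Elba1 and halo, at 8.44 ± 8.55 and 8.02 ± 8.57 CPM in controls, were at least 28.1-fold and 26.7-fold lower. Without control 2, the higher control for these genes, the bounds were 23.2-fold, 7.97-fold and 6.52-fold. The cellularization gene bnk was at 0.128 ± 0.182 against 37.8 ± 40.2 CPM, the 2 controls differing widely, and the X chromosome counting gene sisA at 0.292 ± 0.0502 against 14.4 ± 7.87. Elba3 (0.385 ± 0.545 against 10.6 ± 2.39), bard (0.128 ± 0.182 against 16.3 ± 1.92) and the GABA receptor gene GABA-B-R1 (0.128 ± 0.182 against 6.46 ± 1.02) were also lower. SNCF and bnk were at 0 CPM in the lola-F controls as well, so their levels in the null controls may come from early embryos, as taken up below. The same may hold for Elba1 and halo, at 0 counts in both mutants and with controls that differed widely. The dosage compensation RNA roX1 fell 2.58-fold (adjusted p = 0.0391, but 0.427 without control 1 and 0.655 without control 2), and roX2, Tdc2 and Spn88Ea did not pass (adjusted p = 0.842, 0.514 and 0.245), although Spn88Ea did without null mutant 1 (0.0429). Tbh, at 0.656 ± 0.927 against 0.572 ± 0.422 CPM, was too low to be tested.

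The counts rested on few libraries: 266 higher and 280 lower genes passed without control 2, 345 and 332 without control 1, 1188 and 1924 without the library labelled null mutant 1, and 1559 and 1240 without null mutant 2. Of the 58 named genes that passed, 7 did not without control 1. Without control 2, 55 were tested and 12 of these did not pass; Elba1, halo and RpL22-like were too low to be tested. The median exonic length was 1378 bases for higher and 5005 bases for lower genes, against 2153 bases for all.

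Whether the 2 embryo mutants shared changes was compared next, between sets with separate controls. Of 8807 genes tested in both, 52 were higher in both mutants (17.9 by chance for independent lists, Fisher's exact test, adjusted p = 2.54e-12) and 127 lower in both (32.8 by chance, adjusted p = 1.13e-44), including elav, Sema1a, scrt, Pdp1 and bol. Opposite calls were fewer than chance: 2 genes were higher in lola-F and lower in lola-null (25.9 by chance, adjusted p = 9.96e-10), and 11 were the reverse (22.7 by chance, adjusted p = 0.00744). Across all 8807 genes the log2 fold changes correlated at Pearson's r = 0.33 and Spearman's rho = 0.45. Fold changes ran with transcript length in both sets (rho = −0.50 and −0.49), which by itself adds shared calls and removes opposite ones. No overlap adjusted for length was tested. The Fisher tests also treat genes as independent replicates, which they are not, so their p-values do not measure replication between samples. Without lola-F mutant 1, mutant 2, control 1 or control 2, no gene passed in lola-F embryos by edgeR (2595, 2874, 2277 and 2551 at an unadjusted p under 0.05), so both overlaps were 0; DESeq2 on all libraries gave 96 and 351. The overlaps were 24 and 48 without null control 1, 17 and 45 without null control 2, 129 and 243 without the library labelled null mutant 1, and 64 genes were lower in both without lola-F mutant 3. Without lola-F control 3, 83 were higher in both.

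A test of the difference between the 2 effects found 749 genes with a more positive and 183 with a more negative change in lola-null than in lola-F embryos, of 10848 tested. The split depended on the processing: it was 521 and 521 without a filter on low counts, and 534 and 361 under upper quartile scaling. Cuticle genes stood first: 53 of 93 differed, all more positive in lola-null (camera adjusted p = 3.17e-49, and 0.129 with an estimated correlation). Of 22 neuron genes 1 differed, and camera called the list more negative in lola-null (adjusted p = 0.0156, and 0.664 with an estimated correlation). The counts were 241 and 52 without null control 2, 439 and 103 without null control 1, 283 more positive without lola-F mutant 1, 277 without mutant 2 and 1342 without null mutant 2. They were 92 more negative without lola-F control 1, 438 and 61 without control 2, and 445 and 510 without control 3. The control embryos of the 2 sets, labelled with the same genotype and age, differed in 7381 of 10501 genes (70.3%), 3624 higher and 3757 lower in the lola-null controls. Allele and set thus differ together, and the interaction counts cannot be assigned to the allele alone. The muscle myosin gene Mhc was at 1020 ± 283 CPM in lola-null controls and 8364 ± 655 in lola-F controls.

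**Figure D2:**
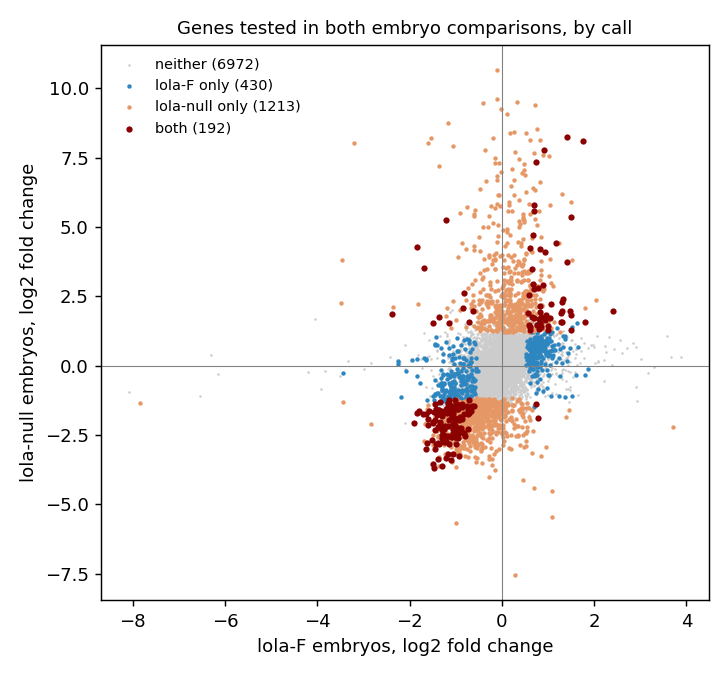
Log2 fold change, mutant minus control, in lola-F embryos (x axis) and lola-null embryos (y axis) for the 8807 genes tested in both, coloured by the set in which a gene passed. Genes called in both lie mostly in the lower left (127) and upper right (52).

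The third comparison asked which genes change in adults when the lola-O isoform is lost. The larval serum protein genes Lsp2 and Lsp1gamma, the yolk protein gene Yp3 and the eye pigment gene cn were higher in lola-O mutant adults. Lsp2 rose 14.1-fold, from 364 ± 43.8 to 5142 ± 354 CPM (adjusted p = 0.0160), and Lsp1gamma 6.03-fold, from 112 ± 33.5 to 673.8 ± 90.8 CPM (adjusted p = 0.0184). Yp3 rose 20.7-fold, from 10.9 ± 3.52 to 223.8 ± 83.1 CPM (adjusted p = 0.00774), and cn, the kynurenine hydroxylase gene, 25.5-fold, from 0.250 ± 0.150 to 6.04 ± 0.0925 CPM (adjusted p = 0.0130). Of 12906 genes tested, edgeR called 43 higher and 29 lower, each by more than 2-fold, and DESeq2 called 164 and 174. Without control 1, Yp3 and cn did not pass (adjusted p = 0.0599 and 0.0862), nor did cn without control 2 (0.0529).

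Of 14 fat body genes, 3 rose (Yp3, Lsp2 and Lsp1gamma) and none fell (7 higher and 1 lower adjusted over the list alone), and camera called the list higher (median log2 fold change 0.99, adjusted p = 1.68e-11, and 0.783 with an estimated correlation). Of 147 detoxification genes 4 rose (19 higher and 5 lower adjusted over the list alone), among them Ugt37A3 (5.34-fold), GstE1 (2.30-fold) and GstD2 (3.12-fold), and camera called the list higher (adjusted p = 3.43e-05, and 0.783 with an estimated correlation). Further rises were in the cuticle gene Edg91 (11.9-fold), the immune-induced peptide gene BaraB (4.96-fold), Acsx1R (4.32-fold) and the amylase gene Amy-d (3.02-fold). The antisense transcript CR11538 rose 26.9-fold; the strand setting of the counting is not given in the sources used here, so its reads and those of its partner gene cannot be told apart.

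Falls among genes at 5 CPM or more in a group included CG6788 (20.1 ± 0.599 to 0.642 ± 0.909 CPM, 34.3-fold), CG11598 (10.9-fold), the proton pump subunit gene Vha100-4 (7.80-fold), the metallothionein gene MtnB (4.16-fold), the kinetochore gene Spc105R (4.01-fold), Jhedup (3.41-fold), the glucose dehydrogenase gene Gld (3.27-fold), sit (3.25-fold), yellow-d2 (2.95-fold) and the odorant-binding protein gene Obp56g (2.90-fold). CG6788 did not pass without control 1 or control 2 (adjusted p = 0.163 and 0.0965). Camera called 4 lists without a called member lower: neuron (22 genes, all with a negative fold change, median −0.55, adjusted p = 0.000219), male accessory gland (60 genes, median −0.25, 3 lower adjusted over the list alone, adjusted p = 0.000822), dopamine and serotonin (19 genes, adjusted p = 0.0204) and axon guidance (37 genes, adjusted p = 0.0233). Adjusted over the list alone, no gene passed in the other 3. With an estimated correlation their adjusted p-values were 0.804, 0.919, 0.783 and 0.783. With the length trend removed, the neuron and the dopamine and serotonin lists lost their calls (adjusted p = 0.112 and 0.0915) and the axon guidance list turned higher without one (adjusted p = 0.428). Without mutant 2 the axon guidance, neuron and accessory gland lists lost their calls (adjusted p = 0.122, 0.0573 and 0.0771), without control 1 the dopamine and axon guidance lists (0.468 and 0.0857), and without control 2 the accessory gland list (0.328).

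Innate immunity genes, a process of interest for lola-O, were not called as lists: of 34 antimicrobial peptide genes BaraB alone rose (list adjusted p = 0.636; 2 higher and 2 lower adjusted over the list alone), and none of 39 Toll and Imd pathway genes or 30 serpin genes passed, over the list alone included. The serpin gene Spn88Ea was at 48.8 ± 8.71 against 46.9 ± 7.29 CPM (log2 fold change 0.06 ± 0.21 SE, adjusted p = 0.921). Tbh, Tdc2, roX1 and roX2 did not pass either (adjusted p = 0.477, 0.951, 0.286 and 0.862), although roX1 did without control 2 (0.0456), and Yp1 was at 0.102 ± 0.0303 against 0.0954 ± 0.0330 CPM. Without control 1, 4 genes were higher and 1 lower, and without control 2, 13 and 52. Without mutant 1 or mutant 2 the counts were 80 and 147, and 156 and 71. Of 22 named genes that passed, 19 did not without control 1 (Lsp2 and Lsp1gamma among the 3 that did), 14 without control 2, 3 without mutant 1 and 1 without mutant 2.

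**Figure D3:**
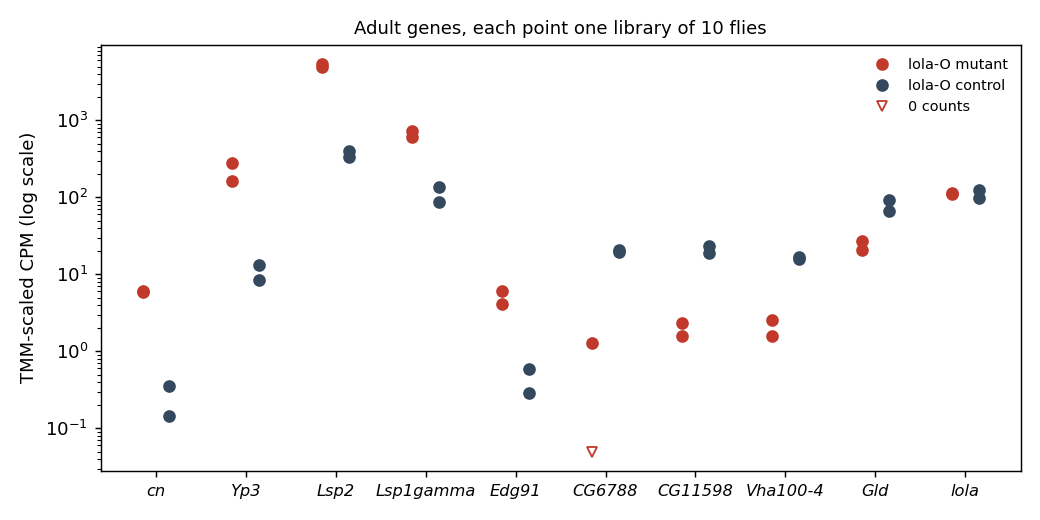
Levels of 10 genes in the 4 lola-O libraries (y axis, TMM-scaled CPM on a log axis; each point is 1 library, open triangles mark a count of 0). Lsp2 and Yp3 are higher in both mutant libraries, CG6788 is lower, and lola overlaps between the groups.

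**Figure D4:**
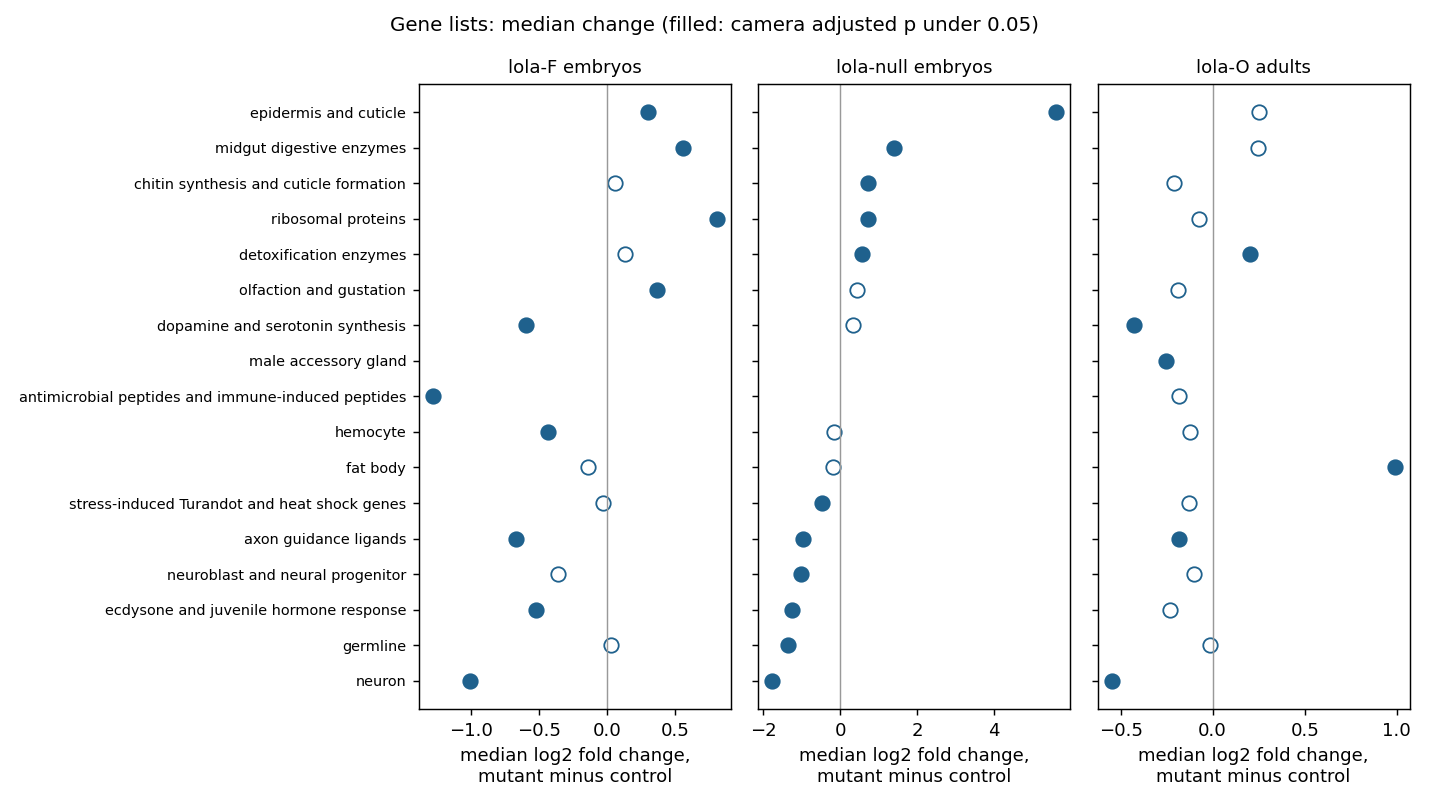
Median log2 fold change, mutant minus control, of each gene list called in at least 1 comparison (x axis) for the 3 comparisons; filled points passed camera at an adjusted p under 0.05 with the preset correlation, and none passed with an estimated one. The cuticle list in lola-null embryos stands at 5.61 (5.35 with the 8 genes without control counts at their floor), and the neuron list is negative in all 3 comparisons.

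The position of called genes was compared with the mutated locus, since mutant and control chromosomes can differ nearby. Within 1 Mb of lola, 9 of 218 tested genes were called in lola-F embryos, 33 of 186 in lola-null embryos and 1 of 238 in lola-O adults, and no difference from the rest of the genome passed (Fisher's exact p = 0.107, 0.767 and 1). By chromosome arm, called genes in lola-null embryos were more frequent on X (19.7% of genes against 16.4% elsewhere, adjusted p = 0.0170) and less frequent on 2R (14.3% against 17.6%, adjusted p = 0.0118).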

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

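The tests on embryo age (cuticle and neuron genes) and on muscle genes were chosen after related values had been seen; the early gene list was written before its values were looked at, but its interval was added after the share was seen.

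The effects of the 2 embryo mutants differed for 749 genes with a more positive and 183 genes with a more negative change in lola-null embryos, by the interaction test. The sets differed in their controls as well as in the allele, so the test cannot assign these differences to the allele. The 5 smallest p-values belonged to Cpr56F, with a log2 difference between effects of 6.61 ± 0.40 (SE), Cpr65Ec (11.4 ± 0.64), Cpr67Fa2 (8.44 ± 0.60), CG13063 (5.55 ± 0.40) and TwdlL (7.10 ± 0.52). The values of Cpr65Ec, at 0 CPM in both null controls, and of Cpr67Fa2, at 0 and 0.137 CPM, are fitted ones that depend on the prior count and are neither sizes nor bounds of the difference. In lola-F embryos these genes had log2 fold changes of 0.51, −0.11, −0.37, −0.31 and 1.40. Each of the 5 differences passed in all 17 alternative fits, those without 1 library included, although the counts fell to 241 and 52 without null control 2 and reached 1342 without null mutant 2 and 510 without lola-F control 3.

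A first hypothesis for the lola-null pattern, cuticle genes higher and neuron genes lower, is that the null control embryos were younger than the mutants. The lola-F controls, with Mhc at 8364 against 1020 CPM, served as an assumed older reference, and of 13 neuron genes that fell in lola-null embryos, 11 were higher in lola-F controls than in lola-null controls, such as nSyb (273.3 against 27.2 CPM with both sets scaled together, and 4.34 in null mutants), and 1, elav, was lower. Neuron genes that rise toward the older reference cannot fall by greater age, which argues against age as the cause of the neuron part alone. Other calls ran the way of age, part of which the null controls shared by both differences give without any common cause. Of 615 higher calls 73.7% were higher in lola-F controls, and of 881 lower calls 43.9% were lower there and 21.8% higher. Over all 10501 genes tested between controls, 3757 were higher and 3624 lower in lola-F controls. The germline, axon guidance and neuroblast lists were also lower there than in null controls (17 of 21, 20 of 37 and 10 of 16 genes). Other lists followed less. All 27 cell cycle genes were lower in lola-F controls, but 4 fell in null mutants (median log2 fold change −0.13, camera adjusted p = 0.228). Of 30 neuropeptide genes 29 were higher in lola-F controls, but none of the 7 tested in null mutants passed. For cuticle, 67.3% of 52 genes that rose were higher in the lola-F controls and 10 were lower, no more than the 60 of 80 higher over the whole list, and the same controls are shared, so age and loss of lola cannot be told apart for the cuticle part.

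Blastoderm embryos among the control embryos are a second candidate explanation, given bnk at 7.81 and 55.1 CPM in the controls (both sets scaled together). They would dilute all late tissues alike, but the muscle list had a median log2 fold change of 0.74 against 5.61 for cuticle (5.35 with genes without control counts at their floor), which argues against them as the cause of the cuticle rise. Of 5 testable early genes written down before they were looked at, 40% (2 of 5, exact interval 5.27% to 85.3%) were lower in both mutants than in both controls, too few to decide on the early gene part: the share lies below the 50% set as the bound against blastoderm embryos, but by less than its interval. Of these 5 genes, zen alone was called lower (edgeR adjusted p = 0.000714). The falls of bnk and SNCF, picked after their values were seen, cannot be told apart from blastoderm embryos among the controls. Both were at 0 CPM in the lola-F controls. The same stays open for Elba1 and halo, at 0 counts in the mutants and with controls that differed widely. It was not tested for sisA or Elba3. Loss of lola function, which the design names, stays open for both the cuticle and neuron parts.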

How the results depend on the processing

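The length correction and the crossed block were chosen after seeing the data; the cause of each move was not tested unless stated. Counts below are higher and lower genes.

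For lola-F embryos (339 and 380), they were 943 higher under upper quartile scaling, 198 and 229 without a filter, 810 and 1112 in DESeq2, 162 and 115 with all 14 libraries in 1 fit, 105 and 234 beyond 2-fold, and 166 and 87 after length correction. Leaving out 1 library gave 0 to 504 and 0 to 646. For lola-null embryos (689 and 881), 1 fit of all libraries gave 1035 and 1436, and leaving out 1 library 266 to 1559 and 280 to 1924. For lola-O adults (43 and 29), upper quartile scaling gave 77 higher, no filter 212 and 203, the 5 CPM filter 17 lower, DESeq2 164 and 174, 1 fit of all libraries 24 and 12, length correction 77 and 57, and leaving out 1 library 4 to 156 and 1 to 147. For the interaction (749 and 183), upper quartile scaling gave 361 negative, no filter 521 negative, DESeq2 333 negative, and leaving out 1 library 241 to 1342 and 52 to 510. Between controls, counts stayed within 1.5-fold in every setting (2944 to 3661 and 3233 to 3848 without 1 library).

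Genes higher and lower in both embryo mutants (52 and 127) were 19 higher beyond 2-fold, 96 and 351 in DESeq2, and 0 to 129 and 0 to 243 without 1 library. The correlation of fold changes (0.33) was 0.37 for genes at 5 CPM or more, and 0.23 to 0.39 without 1 library.

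Called lists (10, 11 and 6) were 0 in each comparison with an estimated correlation, 2, 3 and 0 in fry, and 5 for lola-F after length correction; without 1 library they were 10 to 12, 9 to 11 and 5 to 12. Fry asks whether a list's genes move 1 way on balance, without comparing them with other genes. Length correction turned the ribosomal list of lola-null (adjusted p = 0.889), the axon guidance list of lola-O (0.428), and dpy (log2 fold change 0.0065), Msp300 (0.22) and EcR (0.063) of lola-F; no other named gene or list that had passed turned. Of named genes that had not passed, lola turned from −0.73 to 0.76 in lola-F and from −0.78 to 0.84 in lola-null, Tbh from −0.22 to 0.0016 in lola-F and Spn88Ea from 0.06 to −0.04 in lola-O. Length correction also ended the calls of 6 lists in lola-F, 3 in lola-null and 2 in lola-O, besides those that turned.

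Same-numbered libraries did not deviate together in the embryo sets: correlations of deviations were −0.0165, −0.204 and −0.117 in lola-F and −0.316 in lola-null. In lola-O the correlation was 0.0987 for same-numbered and −0.0987 for crossed pairs. With a replicate block, lola-F counts were 0 and 0 (edgeR, 2494 genes at an unadjusted p under 0.05), lola-null 549 and 630, lola-O 271 and 398, and the interaction 388 and 47. Crossed numbers gave lola-null 862 and 1233. At the depth of the lola-null set, 6% of simulated 2-fold changes were recovered.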

Other observations

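The length correction, the gene lists between control sets and both tests on adults were chosen after the data were seen; the matched-list and age tests were set before their own results, but after the length trend had been seen.

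The control embryos of the 2 sets, labelled with the same genotype and age, differed in lists of many tissues. Compared with lola-F controls, all 27 cell cycle and DNA replication genes were higher in lola-null controls, such as the mitotic phosphatase gene stg (110.9 ± 35.6 against 8.70 ± 1.11 CPM), as were 17 of 21 germline, 10 of 16 neuroblast and 20 of 37 axon guidance genes. Lower in lola-null controls were 46 of 52 midgut enzyme genes, such as Jon44E (0.0908 ± 0.128 against 175.6 ± 26.6 CPM), 29 of 30 neuropeptide genes, 60 of 80 cuticle genes (12 were higher), 17 of 22 muscle genes, such as Act57B (1772 ± 445 against 9073 ± 520 CPM), 18 of 22 neuron genes and all 12 octopamine and tyramine genes, Tbh among them (0.477 ± 0.352 against 28.8 ± 6.72 CPM). Of 30 lists tested, camera called these 10 among others (largest adjusted p = 0.0120), and none passed with an estimated correlation (adjusted p = 0.435 to 0.493). These genes were chosen for display after their values were seen.

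In lola-F embryos, the lower neuron list (median log2 fold change −1.01) and the higher ribosomal protein list (0.80) went with transcript length, which suggests a length bias between libraries as a candidate cause. Among 10000 random lists matched on length and mean expression, the neuron median stood at percentile 0 (matched median −0.56) and the ribosomal median at percentile 100 (matched median 0.37). Lists matched on length thus fell short of both medians. The random lists hold unrelated genes, however, whereas members of these 2 lists vary together (estimated correlations 0.917 and 0.814). The percentiles therefore cannot tell a mutant effect from other differences between libraries that a list shares. Axon guidance genes stood at percentile 7.53 and cuticle genes at 85.4, within what length alone gives. After length correction the neuron list kept its call (adjusted p = 0.00738), as did the midgut, antimicrobial peptide and ribosomal lists, whereas the axon guidance list (0.372) and 5 others lost theirs; without the correction none of the 10 was called with an estimated correlation (adjusted p = 0.783 for each). Of the 719 called genes, 177 remained called after the correction. A difference in embryo age along the axis between the 2 control sets fitted poorly: with no library on both sides, its correlation with the lola-F effect across 9989 genes was −0.0411, 0.0276 and 0.0970 in 3 rotations, so loss of lola-F and other differences between the groups stay open.

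For the 719 genes called in lola-F embryos, the 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05; 1 split, the real one, gave as many genes, and the highest of the others called 1.

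In lola-O adults, the rise of larval serum protein genes and Yp3 could come from a larger share of females or from flies frozen sooner after eclosion. An exchange of sexes large enough for a 14.1-fold rise would lower testis genes, but their median log2 fold change over 69 genes was −0.0527 (95% interval −0.167 to 0.0617), which argues against it, although the male accessory gland median was −0.25. The cuticle list, which would rise in younger flies, had a median log2 fold change of 0.25 and an adjusted p of 0.0591, which does not settle it. Time since eclosion within the 10 h window and loss of lola-O cannot be told apart here, because the labels give no finer age.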
